A study of Mus musculus with 10 samples.

How the data were processed

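Gene expression was measured on Affymetrix arrays in total RNA from the ventral telencephalon of mouse embryos at embryonic day 14.5. The labels put 5 arrays in a wild type group (replicates 1, 2, 5, 21 and 22) and 5 in an Arx mutant group (replicates 11 to 15). Per the labels' protocols, the embryos came from 3 heterozygous dams mated with wild type males, the meninges and the olfactory bulbs were taken off, and the cortex was cut away from the ventral piece. The labels give no sex, litter or scan batch for an embryo and do not say which part of the Arx gene the mutation removes. They describe the same dissection for 5 embryos of each genotype, so each array was taken as 1 embryo.

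The values used are the log2 signals per probe set that the authors deposited, which were made with RMA (background correction, normalization between arrays and summary over the probes of a probe set) per the submitters' processing notes. The RMA software, its version and the scanner settings are not given in the sources used here. That the scale is log2 was read from the values, which ran from 1.56 to 13.55 with array medians of 4.53 to 4.57. Scanner files were not used here. Because RMA had already aligned the distributions of the arrays, a change in the total amount of RNA per embryo leaves no trace in these values, and the precision of each comparison is set by the number of arrays.

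The table held 45101 probe sets. After 64 Affymetrix control probe sets were left out, 45037 were tested. Of these, 34945 named 1 gene in the platform annotation, 932 named several and 9160 named none. The gene identifier was found in a RefSeq gene table of assembly GRCm38.p6 for 34741 of the probe sets with 1 gene and was not found for 204. The table changed 0 symbols. Probe sets with several genes or none entered the probe set fit and named no gene. No coordinates are given, because probe sets were named through identifiers only. None of the probe sets named Arx alone, so the level of the targeted gene was not analysed here and could not be used to check the labels. Ddx3y was likewise not measured.

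Differences between the groups were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The probe set fit used all 45037 probe sets with no filter on dim ones. The gene fit was made on 18193 genes, each represented by the probe set with the highest mean over all 10 arrays among those naming that gene alone. All differences are mutant minus wild type on the log2 scale, with the standard error of the fit, and folds are 2 to the power of that difference, which in RMA values tends to understate the change of dim genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

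Gene lists for cell types, pathways and other tissues were fixed before the data were examined. Of these, 25 lists with at least 5 measured genes were tested with camera from limma at a preset correlation between genes of 0.01, with adjustment over the 25 lists. Sex-linked genes and 4 genes reported as repression targets of Arx were kept out of that family. For each list the members past the threshold were counted with adjustment over all genes and adjusted over the list alone. Genes named in the text came from a rule that was also fixed beforehand. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap on any array, up to 4 members per list with the smallest p among those past the threshold (the 2 smallest where none passed), the sex-linked genes and the reported targets. The rule gave 112 genes, of which 0 had a probe set past the threshold in the opposite direction. Members of the fixed lists that are named outside the rule, namely P2ry12, Maf, Calb2, Nkx2-1, Dlx1, Gad1, Gad2, Drd1, Drd2, Chat, Tbr1, Neurod6, Ptch1, Shh, Sox10 and Tubb3, were chosen after their values were seen. They were not followed through the other settings.

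Each step was tested on simulated data made from the real means and spreads, with 200 changed features. In the gene fit of 18193 genes, 75% of the changes of 0.5 and 100% of the changes of 1 on the log2 scale were recovered, and 6.9% of the calls were not among the changed genes. In the fit of 45037 probe sets the shares were 57%, 95% and 3.2%. The list test found the shifted list and called 0 of the lists that shared no gene with it. The simulated genes varied independently, whereas the real lists held correlated genes (estimated correlation 0.68 for the meninges list). The simulation therefore cannot show how many lists such correlation would call falsely. Arrays were compared in pairs for duplicates. The closest pair, mutant 12 and 13, had a correlation across probe sets of 0.9969 and an SD of the differences of 0.20, close to other pairs within a group, so all 10 arrays were counted. The labels name no litter or day by which arrays could be blocked.

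The choices varied were the scaling between arrays, a filter on dim probe sets, the exclusion of probe sets with the suffixes _x_at, _s_at and _a_at, eBayes with a trend and robust settings, array weights, a Welch test per probe set, stricter thresholds, the probe set taken for a gene, the sex-linked genes, the set test, and each array left out in turn. After the data were seen, further settings were added. These were the Xist level of each array as a covariate, wild type 5 alone against the mutants, the mean of the choroid plexus or of the meninges list as a covariate, wild type 1 and 5 left out together, wild type 1 and 5 alone against the mutants, and the lists of other tissues left out. In every setting with fewer arrays the probe set of a gene stayed the one chosen on all 10 arrays. The list means used as covariates kept all their members, also where a member itself was tested.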

Results

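Arx encodes a homeodomain transcription factor of the developing forebrain, and the series asks whether it acts in the ventral telencephalon mainly by repressing other genes. Expression was compared between 5 wild type and 5 Arx mutant mouse embryos of the same embryonic day, with 1 array per embryo. Array medians lay between 4.53 and 4.57 on the log2 scale, and within-group correlations between arrays had medians of 0.9938 to 0.9965, against 0.9887 to 0.9909 between groups. A first principal component with 46.4% of the variance separated the groups. The second, with 14.1%, set wild type 1 and 5 (25.9 and 29.9) apart from wild type 2, 21 and 22 (-13.7, -23.8 and -11.5). The 3' to 5' signal difference of the Gapdh control probe sets differed by 0.04 between groups (exact permutation p = 0.381, 252 splits, 2-sided), and that of actin by -0.01 (exact permutation p = 0.857).

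In the mutant tissue, 8 of 19 genes of interneurons that leave the ventral telencephalon fell and 3 rose (adjusted p = 0.242 for the list with an estimated correlation), and several genes of striatal neurons and of connective, vascular and immune tissue were higher. Somatostatin (Sst), a peptide of cortical interneurons, fell from 7.60 ± 0.17 to 5.72 ± 0.25 (log2, mean ± SD, n = 5 each), a difference of -1.88 ± 0.12 (SE, limma adjusted p = 1.19e-07). The cell cycle inhibitor Cdkn1c rose from 9.65 ± 0.10 to 10.90 ± 0.07, or 2.37-fold (log2 difference 1.25 ± 0.06, limma adjusted p = 3.05e-08). The retinoic acid receptor gene Rarb rose 5.04-fold (2.33 ± 0.12, limma adjusted p = 3.78e-08). The collagen gene Col3a1 rose 43.6-fold (5.45 ± 0.61, limma adjusted p = 2.67e-05). Its level was 8.61 on wild type 1 and, on the other wild type arrays, 4.44 to 5.93, and without wild type 1 the difference was 6.17.

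Of 18193 genes, 2700 differed between the groups at an adjusted p under 0.05 in limma. Of these, 1744 were higher and 956 lower in the mutants, so that 64.6% were higher. At least 2-fold differences were seen in 360 genes, 338 higher and 22 lower. At the level of probe sets, 3984 of 45037 differed, 2661 higher and 1323 lower. The groups did not overlap on any array for 2300 genes, or 12.6% of all genes, where chance gives 0.79%. Other scalings of the arrays brought the share of higher genes to between 56.8% and 59.1%. The gene count fell to 546 with the Xist level of each array in the model, to 833 with the choroid plexus mean, to 1047 against wild type 5 alone, and to 5 with the meninges mean, which correlated with the group at r = 0.975. With that mean in the model none of the 111 named genes that had passed did so in the same direction, 69 of them keeping at least 50% of their difference while the median SE went from 0.11 to 0.45.

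Among the largest rises were Col3a1, Lum, Col1a2 and Col1a1 of the meninges list, beside genes that are on none of the fixed lists. After Col3a1, Lum rose 31.2-fold (4.96 ± 0.41), Col1a2 20.9-fold (4.39 ± 0.41), Cldn11 19.5-fold (4.29 ± 0.25) and F13a1 17.8-fold (4.15 ± 0.26). Islr, Col1a1, Lyve1, Tbx18, Itih5 and Lox rose by between 12.7-fold and 17.7-fold. With the mean of the probe sets of each gene the differences were smaller for Col3a1 (4.84), Col1a2 (3.08), Col1a1 (2.79), Lyve1 (2.74), Itih5 (2.51), Lox (2.33), Prr15 (-0.57) and Eya4 (-0.66), and all passed. Dct, which encodes an enzyme of melanin synthesis that is also made in forebrain progenitors, fell from 8.58 ± 0.19 to 5.55 ± 0.18 (-3.03 ± 0.10, limma adjusted p = 1.59e-09). Nxph2, encoding a neurexophilin, fell by 2.77 ± 0.12 on the log2 scale, Dmrta1 by 2.22 ± 0.10 and Rpp25 by 2.00 ± 0.10. Falls of Rbm20 (-1.61 ± 0.13), Prr15 (-1.57 ± 0.24), Eya4 (-1.54 ± 0.12) and Rec8 (-1.41 ± 0.11) followed. The call of Prr15 ended with the Xist level or the choroid plexus mean in the model (-1.71 and -1.42).

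Genes of the meninges, blood vessels and microglia were higher in the mutants as groups. All 15 measured genes of the meninges list rose, with a median difference of 3.06 (camera adjusted p = 8.98e-30, and adjusted p = 0.0412 with an estimated correlation). Examples were the transporter gene Slc6a13 (9.70-fold, 3.28 ± 0.13), the transcription factor gene Foxd1 (5.68-fold, 2.51 ± 0.10) and the matrix gene Dcn (10.9-fold, 3.44 ± 0.17), of which 1 of 2 probe sets passed and whose mean over probe sets differed by 1.71. All 15 genes of the blood vessel list rose, with a median of 1.29 (camera adjusted p = 3.94e-24, and adjusted p = 0.0101 with an estimated correlation), among them the pericyte gene Pdgfrb (1.96 ± 0.10) and the endothelial genes Cldn5 (1.73 ± 0.09) and Tek (1.86 ± 0.11). Of 13 microglia genes, 12 rose, with a median of 1.09 (camera adjusted p = 4.17e-16, and adjusted p = 0.00806 with an estimated correlation). They included Csf1r (1.10 ± 0.07), C1qc (1.22 ± 0.08) and Mrc1 (3.61 ± 0.25), while P2ry12, chosen after its value was seen, did not pass (-0.22 ± 0.15).

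Of 9 choroid plexus genes, 8 rose, with a median of 1.93 (camera adjusted p = 2.05e-06, and adjusted p = 0.204 with an estimated correlation). Clic6 rose from 4.24 ± 1.57 to 7.46 ± 0.35, and Folr1, encoding a folate receptor, from 4.41 ± 0.86 to 6.26 ± 0.48, and without wild type 1 the difference of Clic6 was 3.92 in place of 3.22. It was 1.75 without the probe sets with suffixes and 2.49 with the mean of its probe sets. Clic6 and Folr1 did not pass with the Xist level (3.90 and 2.28) or the choroid plexus mean (0.24 and 0.10) in the model, or against wild type 1 and 5 alone (2.06 and 1.23). Both genes are part of the choroid plexus mean, so their loss with it was largely fixed by construction. Counts for the meninges, vessel, microglia and choroid plexus lists adjusted over the list alone were 15, 15, 12 and 8 higher and 0 lower. On wild type 1 the meninges mean lay 0.98 and the choroid plexus mean 1.87 above the wild type mean, where the mutant arrays lay 3.08 to 3.43 and 1.81 to 2.54 above it. Of 9 red blood cell genes, 2 rose, Alas2 (0.99 ± 0.11) and Slc4a1 (0.57 ± 0.09, which did not pass with the Xist level, 0.55, the choroid plexus mean, 0.62, or against wild type 5 alone, 0.54), the same 2 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.552), its median of -0.08 and its mean of 0.09 differing in sign.

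**Figure D1:**
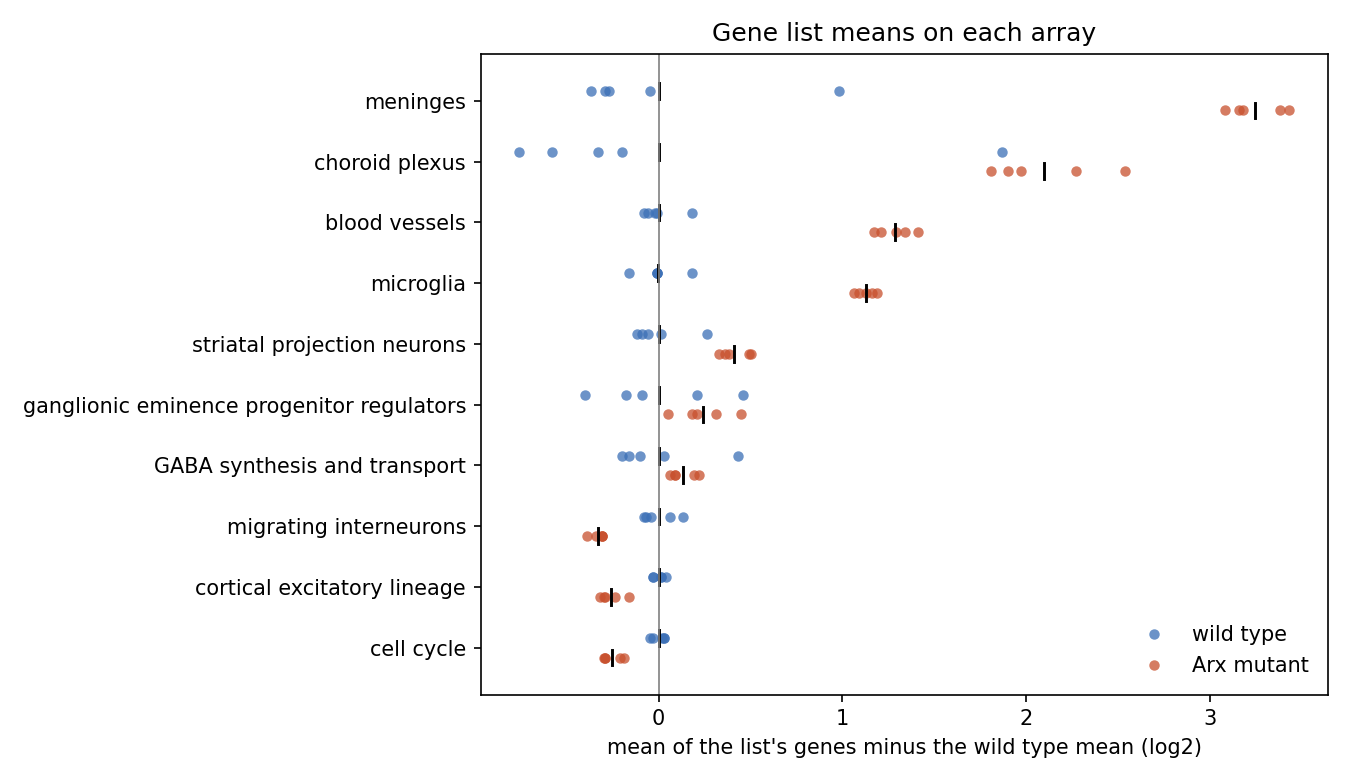
The mean log2 signal of each gene list on each array is plotted as its distance from the wild type mean, with wild type arrays in blue, Arx mutant arrays in orange and group means as black bars. The meninges means of the mutant arrays lie 3.08 to 3.43 above the wild type mean, wild type 1 lies at 0.98, and the migrating interneuron means of the mutants lie at -0.39 to -0.31.

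The sex-linked genes also differed between the groups. Xist, the transcript that silences an X chromosome in female cells, fell from 8.31 ± 1.73 to 3.95 ± 0.20 (-4.36 ± 0.61, limma adjusted p = 0.000222). It stood at 8.96 to 9.26 on 4 wild type arrays and at 5.22 on wild type 5. The Y-linked genes Eif2s3y (3.80 ± 0.65), Kdm5d (3.89 ± 0.78) and Uty (1.83 ± 0.36) rose, and wild type 5 carried them at 6.55, 7.12 and 5.83, where the mutant means were 7.10, 7.11 and 5.93. Without wild type 5 the differences of Xist, Eif2s3y and Kdm5d were -5.14, 4.61 and 4.86. With the mean of probe sets those of Xist, Eif2s3y, Kdm5d and Uty were -3.68, 2.09, 1.86 and 1.10. Adjusted over the list alone, the counts were the same, 3 higher and 1 lower. The labels give no sex, and the sex-linked transcripts differed between 4 of the 5 wild type arrays and all mutant arrays. By these transcripts those 4 arrays had a female pattern, and wild type 5 and the mutants a male one. Sex and genotype thus nearly coincided, and wild type 5 was the only array in which they parted.

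The 4 genes known from reports as repression targets of Arx were all measured. Cdkn1c is given above, Lmo1, a LIM-only cofactor gene, rose 1.63-fold (0.71 ± 0.06, limma adjusted p = 1.92e-06), and Ebf3, a neuronal transcription factor gene, rose 1.45-fold (0.53 ± 0.08, limma adjusted p = 0.000421). Shox2 was at 2.67 ± 0.04 and 2.85 ± 0.13 (0.18 ± 0.07, limma adjusted p = 0.107), near the low end of the scale. Thus 3 of the 4 passed over all genes and 4 when adjusted over the list alone. Reports that name them may rest on these same samples, so the list is not independent evidence of its direction. Ebf3 did not pass with the Xist level in the model (0.71) or with the choroid plexus mean (0.52), and Shox2 passed after quantile normalization was applied once more (0.23). With the meninges mean in the model Cdkn1c (0.89 ± 0.29) and Lmo1 (0.93 ± 0.28) did not pass.

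Of 19 genes of migrating interneurons, 8 fell and 3 rose (adjusted over the list alone, 8 fell and 4 rose). Apart from Sst, the falls included Nxph1 (-1.59 ± 0.08, limma adjusted p = 1.92e-08), the LIM homeobox gene Lhx6 (-1.51 ± 0.25, limma adjusted p = 0.000785), the neuropeptide gene Npy (-0.98 ± 0.13) and the transcription factor gene Sox6 (-0.69 ± 0.09). The list as a whole was lower, with a median of -0.15 (camera adjusted p = 0.0138), but not with an estimated correlation (adjusted p = 0.242 with an estimated correlation). The guidance receptor gene Robo1 (0.67 ± 0.10), Maf (0.61 ± 0.13) and Calb2 (0.74 ± 0.17) were the members that rose, the last 2 of them named after their values were seen. Against wild type 5 alone the list did not pass (median -0.11, adjusted p = 0.323, in a range of 0.00255 to 0.483 over the added settings and 0.000228 to 0.242 over those set before the data were examined), nor did Lhx6 (-1.34), whereas Sst (-2.05), Nxph1 (-1.45), Sox6 (-0.73) and Npy (-1.08) passed. With the Xist level in the model Sst (-2.10) and Nxph1 (-1.40) passed, and the list (median -0.06), Lhx6 (-1.31), Sox6 (-0.79) and Npy (-1.08) did not. The choroid plexus mean ended the calls of the list (median -0.30), Lhx6 (-1.40) and Npy (-0.82). The list did not pass either on ranks, in probe sets at or above the median, without the probe sets with suffixes or against wild type 1 and 5 alone (medians -0.15, -0.13, -0.10 and -0.21). The meninges and vessel means were higher on the same mutant arrays by 3.25 and 1.28.

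**Figure D2:**
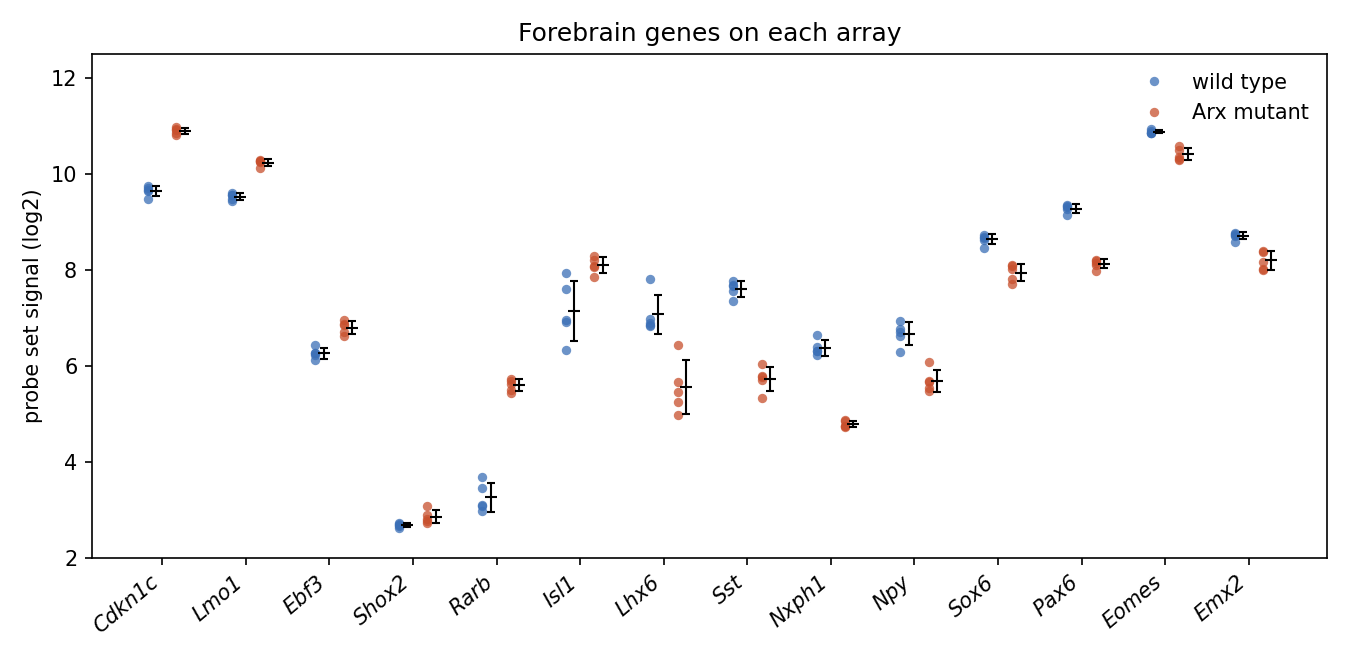
The log2 signal of 14 forebrain genes is plotted for each wild type array (blue) and each Arx mutant array (orange), with group means and SD in black (n = 5 each). Cdkn1c, Lmo1 and Rarb lie higher and Sst, Nxph1 and Pax6 lower on every mutant array than on any wild type array, while the groups overlap for Isl1.

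Regulators of ganglionic eminence progenitors did not move as a group (14 measured, median 0.18, camera adjusted p = 0.151, and adjusted p = 0.659 with an estimated correlation). Otx2, which is also on the choroid plexus list (1.22 ± 0.19), Olig1 (0.83 ± 0.19) and Olig2 (0.90 ± 0.23) rose and Sp8 (-0.88 ± 0.16) fell, or 4 and 1 adjusted over the list alone. Nkx2-1, the regulator of the medial eminence, was at 4.15 and 4.09 (-0.06 ± 0.15), and Dlx1 at 8.70 and 9.13 (0.44 ± 0.19), both chosen after their values were seen. Nkx2-1 lay below the array medians of 4.53 to 4.57, so its lack of change says little. Without wild type 22, whose list mean was 0.46 above the wild type mean, this list passed (median 0.33), as it did without mutant 11 (median 0.24), against wild type 5 alone (median 0.27) and against wild type 1 and 5 alone (median 0.19). With the choroid plexus mean in the model, which was 2.10 higher on the mutant arrays, Otx2 (0.71), Sp8 (-0.24), Olig1 (1.15), Olig2 (0.98) and Slc12a2 (0.22) did not pass. Otx2 is itself part of that mean. With the Xist level, Otx2 (1.56), Sp8 (-0.74), Olig1 (1.28), Slc12a5 (0.98) and Slc12a2 (0.39) did not pass. Slc12a2 did not pass against wild type 5 alone (0.39) or wild type 1 and 5 alone (0.32), nor did Olig1 without wild type 1 and 5 (0.63). Of 7 genes of GABA synthesis and transport, the chloride transporter genes Slc12a5 (0.89 ± 0.12, and 0.43 at its lowest over the settings chosen beforehand) and Slc12a2 (0.41 ± 0.07) rose, 2 also adjusted over the list alone. The synthesis genes Gad1 (-0.10 ± 0.15) and Gad2 (-0.02 ± 0.19), chosen after their values were seen, did not pass. That list as a whole did not pass (camera adjusted p = 0.294), its median of -0.02 differing in sign from its mean of 0.13 and its test, but it did without wild type 22 (median 0.17), with the choroid plexus mean in the model (median 0.30), against wild type 5 alone (median 0.16) and against wild type 1 and 5 alone (median 0.26).

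Genes of striatal projection neurons were higher as a group (18 measured, 8 higher and 1 lower, the same counts adjusted over the list alone, median 0.23, camera adjusted p = 0.00109, and adjusted p = 0.227 with an estimated correlation). Beside Rarb, the opioid precursor gene Penk (0.70 ± 0.12), Foxp2 (0.52 ± 0.11) and Ebf1 (0.66 ± 0.14) rose, whereas the dopamine receptor genes Drd1 (0.15 ± 0.13) and Drd2 (0.27 ± 0.14), chosen after their values were seen, did not pass. Of 10 cholinergic genes, 4 rose (5 adjusted over the list alone), among them Isl1, a LIM homeobox gene shared with striatal neurons (0.95 ± 0.23), and the neurotrophin receptor gene Ngfr (0.50 ± 0.12). The acetylcholine synthesis gene Chat, also chosen in that way, was at 2.88 and 2.74 (-0.14 ± 0.10), near the low end of the scale. The cholinergic list did not pass (median 0.24, camera adjusted p = 0.0932, and adjusted p = 0.532 with an estimated correlation). It passed without wild type 22 (median 0.49), without mutant 12 (median 0.28), against wild type 5 alone (median 0.37) and against wild type 1 and 5 alone (median 0.48). It also passed after quantile normalization once more (median 0.25), in probe sets at or above the median or the 25th percentile (median 0.50 in both) and with the most variable probe sets (median 0.29). Penk did not pass with the Xist level (0.29) or the choroid plexus mean (0.79) in the model, or against wild type 5 alone (0.46). Foxp2 (0.72), Ebf1 (0.98), Isl1 (1.15) and Ngfr (0.47) did not pass with the Xist level. Isl1 (1.21) and Ngfr (0.22) did not pass with the choroid plexus mean, nor Ngfr against wild type 5 alone (0.54), against wild type 1 and 5 alone (0.42) or with the mean of its probe sets (0.24), nor Isl1 without wild type 1 and 5 (0.82). The striatal list did not pass in probe sets at or above the median (median 0.20). At the preset correlation it passed with the Xist level (median 0.46), the choroid plexus mean (0.48) or the meninges mean (0.75) in the model. The meninges mean was 3.25 higher on the same mutant arrays.

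Of 10 genes of the dorsal lateral eminence and olfactory interneurons, 4 fell and 2 rose (4 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.532), its median of 0.03 differing in sign from its mean of -0.06 and its test. By fry, another set test, the list passed as lower (fry adjusted p = 0.0351). Pax6, a regulator of dorsal progenitors, fell from 9.28 ± 0.08 to 8.12 ± 0.09 (-1.16 ± 0.07, limma adjusted p = 7.07e-08), and Nr2f1 fell by 0.67 ± 0.13 on the log2 scale. Tshz2 rose (1.14 ± 0.13, and 0.61 at its lowest over the settings chosen beforehand). In the cortical excitatory lineage 8 of 16 genes fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 1.93e-05, and adjusted p = 0.0784 with an estimated correlation). At the preset correlation the list also passed with the Xist level (median -0.22), the choroid plexus mean (-0.21) or the meninges mean (-0.41) in the model. The mean of this list was 9.50 on the wild type arrays, although the labels describe the cortex as cut away. How much cortex the pieces of each group held was not tested. Besides Pax6, the intermediate progenitor gene Eomes (-0.47 ± 0.07) and Emx2 (-0.51 ± 0.09) fell, and the neuronal genes Tbr1 (-0.07 ± 0.09) and Neurod6 (-0.10 ± 0.08), chosen after their values were seen, did not pass. Nr2f1, Eomes and Emx2 did not pass with the Xist level in the model (-0.38, -0.47 and -0.54) or against wild type 5 alone (-0.44, -0.45 and -0.52), nor Nr2f1 (-0.65) and Emx2 (-0.59) with the choroid plexus mean, nor Nr2f1 against wild type 1 and 5 alone (-0.58). The meninges mean was 3.25 higher on the same mutant arrays.

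Genes of Cajal-Retzius cells and the cortical hem did not shift as a list (13 measured, 4 higher and 1 lower, the same adjusted over the list alone, median 0.10, camera adjusted p = 0.208). The transcription factor gene Ebf2 (1.00 ± 0.15) and the hem gene Wnt8b (0.99 ± 0.21) rose, and Trp73 fell (-0.44 ± 0.06). Of 17 genes of the diencephalon and hypothalamus, Tcf7l2 (0.99 ± 0.16), Barhl2 (0.62 ± 0.12) and Irx3 (0.51 ± 0.10) rose and 0 fell (4 and 0 adjusted over the list alone), and the list did not pass (median 0.13, camera adjusted p = 0.178), except with the most variable probe set of each gene (median 0.15). The difference of Tcf7l2 was 0.42 at its lowest over the settings chosen beforehand. Ebf2, Wnt8b, Tcf7l2, Barhl2 and Irx3 did not pass with the Xist level in the model (0.49, 0.38, 0.52, 0.48 and 0.19) or against wild type 5 alone (0.58, 0.53, 0.70, 0.52 and 0.28). With the choroid plexus mean, 2.10 higher on the mutant arrays, Wnt8b (0.32), Trp73 (-0.37), Tcf7l2 (0.72) and Irx3 (0.38) did not pass, nor did Wnt8b (0.50) and Irx3 (0.30) against wild type 1 and 5 alone.

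Cell cycle genes were lower in the mutants. Of 22 measured, 17 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 5.34e-08, and adjusted p = 0.0873 with an estimated correlation). At the preset correlation the list also passed with the Xist level (median -0.37), the choroid plexus mean (-0.35) or the meninges mean (-0.36) in the model. The replication genes Mcm6 (-0.44 ± 0.07), Mcm7 (-0.33 ± 0.06) and Rrm2 (-0.39 ± 0.06) fell, and the cyclin gene Ccnd1 rose (0.52 ± 0.08). Among 10 cell cycle inhibitors, Cdkn1c rose and Gadd45g (-0.48 ± 0.10) and Cdkn2c (-0.26 ± 0.07) fell (2 higher and 3 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.657), its median of -0.14 and its test differing in sign from its mean of 0.03. In the radial glia and Notch list, 3 of 18 genes rose and 5 fell (4 and 8 adjusted over the list alone). This list did not pass (camera adjusted p = 0.294), its median of -0.17 and its test differing in sign from its mean of 0.03. Id3 (1.52 ± 0.09) and Id1 (1.05 ± 0.12), which are targets of BMP signalling, rose, and the Notch effector genes Hes1 (-0.72 ± 0.08) and Hey1 (-0.52 ± 0.07) fell. With the Xist level in the model Mcm6 (-0.45), Mcm7 (-0.42), Rrm2 (-0.51), Ccnd1 (0.60), Gadd45g (-0.81), Cdkn2c (-0.37), Hes1 (-0.50) and Id1 (1.02) did not pass. The choroid plexus mean ended the calls of Rrm2 (-0.43), Ccnd1 (0.36), Mcm7 (-0.28), Gadd45g (-0.58), Cdkn2c (-0.40) and Id1 (0.61). Mcm6 (-0.42), Mcm7 (-0.39) and Cdkn2c (-0.33) did not pass against wild type 5 alone, nor did Cdkn2c without wild type 1 and 5 (-0.21). The meninges mean was 3.25 higher on the same arrays.

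Hedgehog pathway genes were lower as a list (11 measured, 4 lower and 1 higher, or 5 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 0.0138, and adjusted p = 0.0873 with an estimated correlation). The co-receptor genes Gas1 (-0.67 ± 0.06), Cdon (-0.52 ± 0.06) and Boc (-0.39 ± 0.08) fell, together with Gli2 (-0.30 ± 0.06). The target gene Ptch1 rose (0.37 ± 0.11) and Shh was at 6.16 and 6.04 (-0.11 ± 0.33), both chosen after their values were seen. Wnt pathway genes went both ways (16 measured, 5 higher and 3 lower, or 5 and 5 adjusted over the list alone, median 0.12, camera adjusted p = 0.532), with a rise of Sp5 (1.10 ± 0.10) and Wnt5a (0.46 ± 0.07) and a fall of the receptor gene Fzd8 (-0.75 ± 0.08). The Hedgehog list did not pass with the Xist level in the model (median -0.12), against wild type 5 alone (median -0.15), against wild type 1 and 5 alone (median -0.26) or on ranks (median -0.18). Cdon (-0.52), Boc (-0.56), Gli2 (-0.38) and Wnt5a (0.54) did not pass with the Xist level. Boc (-0.44), Gli2 (-0.29) and Wnt5a (0.39) did not pass with the choroid plexus mean, nor did Gli2 against wild type 5 alone (-0.38) or with its most variable probe set (-0.36). The meninges and vessel means were 3.25 and 1.28 higher on the same mutant arrays.

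Of 13 retinoic acid pathway genes, 5 rose and 0 fell, the same adjusted over the list alone (median 0.13, camera adjusted p = 0.01, and adjusted p = 0.249 with an estimated correlation). The synthesis gene Aldh1a2, which is also on the meninges list, rose 7.30-fold (2.87 ± 0.21), and Rarb and the retinol transporter gene Stra6 (1.28 ± 0.16) rose with it. The meninges mean was 3.25 higher on these arrays. The list did not pass with the Xist level (median -0.09) or the choroid plexus mean (median 0.22) in the model, against wild type 1 and 5 alone (median 0.07), in probe sets at or above the median (median 0.32) or on ranks (median 0.13). Against wild type 5 alone its median was also negative (-0.07), although the list test still called it higher. Axon guidance genes were higher as a list (34 measured, 9 higher and 1 lower, or 11 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.0127, and adjusted p = 0.296 with an estimated correlation), with rises of Ntn1 (1.33 ± 0.21, and 0.74 with the mean of its probe sets), Slit2 (0.54 ± 0.06) and Sema6a (0.67 ± 0.09). Slit2 did not pass when its most variable probe set was taken (0.16). Stra6 (1.28), Sema6a (0.49) and Ntn1 (0.99) did not pass with the Xist level in the model, nor did Stra6 (0.72) and Sema6a (0.46) with the choroid plexus mean. Sema6a did not pass against wild type 5 alone (0.57) or with its most variable probe set (0.49), and the axon guidance list did not pass without wild type 1 and 5 (median 0.10).

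Of 9 oligodendrocyte precursor genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 0.0192, and adjusted p = 0.196 with an estimated correlation). Pdgfra, a growth factor receptor gene that connective tissue cells also express, rose 10.2-fold (3.35 ± 0.16, and 1.98 with the mean of its probe sets), while Sox10 (-0.13 ± 0.07), chosen after its value was seen, did not pass, and the meninges mean was 3.25 higher on the same arrays. Genes common to all neurons were slightly higher as a list (15 measured, 4 higher and 0 lower, or 5 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.0138, and adjusted p = 0.48 with an estimated correlation). Dcx rose (0.24 ± 0.06), and Tubb3, chosen after its value was seen, was at 11.13 in both groups. The call of Dcx ended without wild type 1 (0.21), without mutant 12 (0.22) and with its most variable probe set (0.01), and also with the mean of its probe sets (0.12), the Xist level (0.26), the choroid plexus mean (0.37), wild type 5 alone (0.24) and without wild type 1 and 5 (0.20). The neuronal list did not pass with the most variable probe sets (median 0.02), the mean of probe sets (median 0.12), probe sets at or above the median (median 0.14), fry (median 0.14) or without wild type 1 and 5 (median 0.11). At the preset correlation it passed with the Xist level (median 0.26), the choroid plexus mean (0.19) or the meninges mean (0.23) in the model. The oligodendrocyte precursor list did not pass on ranks (median 0.35).

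Immediate early and stress genes did not pass as a list (15 measured, 5 higher and 2 lower, the same adjusted over the list alone, median 0.15, camera adjusted p = 0.0972), except against wild type 5 alone (median 0.21) and by fry. The immediate early genes Fos (1.34 ± 0.18) and Egr1 (1.67 ± 0.27) rose and Jun fell (-0.50 ± 0.06). Among 14 hypoxia and glycolysis genes, the glucose transporter gene Slc2a1 (0.53 ± 0.08), which is also on the vessel list, and Pfkp (0.64 ± 0.10) rose, and the list did not pass (3 higher and 0 lower, the same adjusted over the list alone, median 0.03, camera adjusted p = 0.191). Jun (-0.37) and Pfkp (0.70) did not pass with the Xist level in the model, nor Jun against wild type 5 alone (-0.40) or Slc2a1 with the choroid plexus mean (0.48). Fos and Egr1 did not pass with the Xist level (1.41 and 1.60) or the choroid plexus mean (1.02 and 0.88) in the model. The vessel mean was 1.28 higher on the same mutant arrays.

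Of the 25 lists tested, 13 passed, 9 of them higher and 4 lower in the mutants. With an estimated correlation 3 passed, the meninges, vessel and microglia lists, and fry, which tests whether the genes of a list move one way without setting them against other genes, called 15. Of 100 splits of the arrays into groups of 5, 5 gave 13 or more lists, the real one included.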

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

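Of the tests given here, those on the mutant tissue itself, on less ventral tissue, on dilution and on embryo sex were chosen after the result was seen. The tests on carried-over tissue were set once wild type 1 was known to have high choroid plexus and meninges means. A gap of 1 array from the other 4 of its group by Dixon's test was looked for in 278 groups of 5. It was found in 28, where chance gives about 1 in 20 groups, or 13.9. Of the 28, 14 lay in wild type 1 and 5 in wild type 5.

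Wild type 1 stood above the other wild type arrays for several genes of the meninges and choroid plexus lists and for some others. Lum was at 5.75 there (2.81 to 3.38 on the others), Col1a2 at 7.38 (4.73 to 5.11), F13a1 at 5.03 (3.31 to 3.70), Islr at 5.05 (3.75 to 3.98), Col1a1 at 4.95 (3.19 to 3.63) and Itih5 at 4.69 (3.32 to 3.70). Aldh1a2 was at 3.77 (2.59 to 2.77) and the macrophage gene Mrc1 at 4.72 (3.14 to 3.40). The choroid plexus genes Calml4, Clic6 and Folr1 were at 4.87 (2.42 to 2.90), 7.05 (3.37 to 3.75) and 5.94 (3.92 to 4.12). Relative to the wild type mean, the meninges list of this array lay at 0.98 (-0.37 to -0.05), the choroid plexus list at 1.87 (-0.76 to -0.20) and the vessel list at 0.18 (-0.08 to -0.01).

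Wild type 5 stood apart for the sex-linked genes, with Xist at 5.22 (8.96 to 9.26 on the other wild type arrays), Eif2s3y at 6.55 (2.19 to 2.80), Uty at 5.83 (3.42 to 3.91) and Kdm5d at 7.12 (1.93 to 3.04). Its mean of the Cajal-Retzius list was 0.17 above the wild type mean (-0.08 to -0.01). On wild type 22, Lhx6 was at 7.80 (6.83 to 6.97) and the hypoxia list at -0.08 (0.01 to 0.03).

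Among the mutants, Lmo1 was at 10.12 (10.24 to 10.29) and Boc at 7.54 (7.31 to 7.36) on array 11. On array 14, Col1a2 was at 10.24 (9.60 to 9.73), Zic4 at 8.13 (7.89 to 7.96) and Gli2 at 7.98 (8.14 to 8.19). On array 15, Folr1 was at 7.10 (5.94 to 6.21) and Egr1 at 6.50 (7.28 to 7.58).

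The meninges, vessel and microglia means were higher on every mutant array than on any wild type array, whereas the choroid plexus mean of wild type 1 (1.87) lay above that of mutant 13 (1.81). If pieces of these tissues could stay on a sample, a wild type array carrying some would be raised across genes higher in mutants. This was read over 298 genes outside the lists, called at least 2-fold higher in the mutants against wild type 21 and 22 alone. Over them wild type 1 lay a median of 0.30 above wild type 5 and 0.29 above wild type 2. Wild type 2 and 5 differed by 0.03. More covering tissue left on the mutant pieces is compatible with this. But wild type 1 was picked for its high choroid plexus and meninges means, so part of its rise over these genes was built in. The mutants lay a median of 1.5 above wild type 21 and 22, but these arrays also chose the genes, which sets that size in part. A change in the genes of these tissues by the mutant tissue itself stays open, since the lowest mutant meninges mean was 2.10 above the highest wild type mean. For the meninges, vessel and microglia genes these cannot be told apart, because no wild type array reached the mutants, while for the choroid plexus genes 1 wild type array reached the mutant level without the mutation.

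More genes were higher than lower in the mutants, 64.6% of those that differed. Normalization between arrays stays open as part of it, since 3 other scalings gave 56.8% to 59.1%. Among genes changed at least 2-fold the excess hardly moved. There these scalings gave 325 to 332 higher and 25 to 27 lower, against 338 and 22 in the main fit. Genes of carried-over tissue stay open too, since 97.5% of the 237 genes changed at least 2-fold, outside the lists and raised in wild type 1 over wild type 5, were higher, against 81.7% of the 60 that were not raised. Repression by Arx, which the design names, may add to the excess and was not tested apart from these.

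Of 19 genes of migrating interneurons, 8 fell, 3 rose and 8 did not pass (median -0.15, mean -0.33, camera adjusted p = 0.0138, and adjusted p = 0.242 with an estimated correlation). Dilution by tissue without neurons is argued against as the whole cause. The pan-neuronal list lay 0.29 above the interneuron list by the median over members (95% interval 0.16 to 0.41). By the mean it lay 0.47 above (0.37 to 0.57). Dilution by tissue that holds other neurons stays open, because such tissue carries pan-neuronal genes too. Less ventral tissue stays open, because the ganglionic eminence list lay 0.57 above the interneuron list by the mean (0.21 to 0.93) but 0.31 by the median, with an interval from -0.10 to 0.72. Embryo sex stays open, since only wild type 5 had low Xist, where the interneuron list averaged 7.08, or -0.10 from the other wild type arrays (7.09 to 7.29), and 6.86 on the highest mutant, although against that array alone Sst (-2.05) and Nxph1 (-1.45) kept their falls, as they did with the Xist level in the model (-2.10 and -1.40), where the list did not pass (adjusted p = 0.483, in a range of 0.00255 to 0.483 over the added settings). An effect of the mutation on these cells is a candidate explanation that the design names. These values do not separate it from sex, from less ventral tissue or from added tissue that holds other neurons.

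Chance as the reason for the counts was examined with 100 splits of the 10 arrays into 5 and 5, the real one included. The real split alone gave as many genes (1 split, 2700 against at most 9 in the others), as many probe sets (1 split, 3984 against 4) and as large an excess of higher over lower genes (1 split, 788 against 3). A random grouping of these arrays is thus an unlikely reason for these counts. In the other splits the real group difference adds to the spread within groups, so their low counts do not gauge the size of the excess. The splits do not separate genotype from sex or from covering tissue. For the count of lists, 5 splits gave 13 or more, the highest of the others being 13, so chance is not excluded for that count. Each other split mixes the groups unevenly and keeps part of the real difference, which can itself move lists. The splits therefore cannot settle whether chance gave that count.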

How the results depend on the processing

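The settings with Xist, choroid plexus or meninges as a covariate, wild type 5 alone, wild type 1 and 5 left out or alone, and the other-tissue lists left out were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Over the settings chosen beforehand, the named genes gave 2372 values of the same direction and side of the threshold, 67 that no longer passed, 1 that newly passed and 1 that reversed. The lists gave 590, 22, 12 and 1. Over the added settings the genes gave 400 the same, 246 no longer past and 26 reversed, and the lists 122, 18, 8 newly past and 2 reversed. With 1 array left out, counts ran from 2838 to 3656 probe sets, 2009 to 2599 genes and 13 to 16 lists, and the share of higher genes from 63.2% (without wild type 21) to 69.7% (without mutant 12). No list call was lost, but calls near the threshold were. Neurog2 did not pass without mutant 12 (-0.22), Snap25 without wild type 1 (0.34) or mutant 14 (0.33), Zic4 without wild type 1 (0.67) or mutant 14 (0.67), and Zic1, Stmn2, Syt1 and Adm without several arrays each. Genes near the low end of the scale, such as Shox2, are limited by the signal over background.

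The share of higher genes was 56.8% with quantile normalization once more, 59.1% with arrays centred on the median, 58.8% centred on the middle of expression, 62.3% for probe sets at or above the median, 62% with array weights, 62% with the mean of probe sets per gene and 68.7% with the most variable probe set. The stricter thresholds pass fewer genes by construction. An adjusted p under 0.01 gave 2124 probe sets and 1514 genes, 74.9% higher, and at least 1.5-fold gave 1373 and 816, 88% higher. A Welch test gave 2413 probe sets and ended 17 named calls without moving a difference, among them Otx2, Olig1, Olig2, Ebf1, Isl1, Ngfr, Wnt8b, Clic6, Eif2s3y, Kdm5d and Uty (adjusted p 0.0516 to 0.154). With an estimated correlation 3 lists passed. Snap25 reversed with its most variable probe set (-0.07), and the cell cycle inhibitor list by fry (median -0.14). For these the cause was not tested.

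With the Xist level as a covariate (r with the group -0.892), 642 probe sets and 546 genes passed, 79.9% higher, and Eif2s3y (-0.58), Uty (-0.50), Kdm5d (-1.42) and Xist itself (0) reversed or became 0. Against wild type 5 alone, a lone sample assumed to vary like the mutants, 1438 probe sets and 1047 genes passed, 74.2% higher, and Kdm5d was at -0.01. The choroid plexus mean (r = 0.831) gave 1009 and 833, 76.4% higher. Of the named genes, 55, 29 and 49 no longer passed in these 3 settings, with 50, 26 and 43 of them at least 50% as large as before, and the median SE went from 0.11 to 0.23, 0.15 and 0.18. Without wild type 1 and 5 the share was 67.9%, and with them alone 59.7%.

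With the meninges mean as a covariate, which nearly repeats the group (r = 0.975), 2 probe sets, 5 genes (80% higher) and 7 lists passed. These were the blood vessel, microglia, striatal, cortical, cell cycle and pan-neuronal lists, and the choroid plexus list in the opposite direction. Of the named genes, 90 no longer passed, although 40 of these differences were at least as large as before and 69 at least 50% as large, while the median SE went from 0.11 to 0.45. Sst was at -1.96 ± 0.54 (SE), Dct at -2.54 ± 0.47, Nxph1 at -1.36 ± 0.36, Pax6 at -1.02 ± 0.31, Lmo1 at 0.93 ± 0.28 and Cdkn1c at 0.89 ± 0.29. The other 21 reversed, namely Col3a1 (-4.07), Lum (-1.32), Col1a2 (-2.01), Col1a1 (-0.30), Otx2 (-0.42), Sp8 (0.48), Slc12a2 (-0.07), Ngfr (-0.56), Wnt8b (-0.54), Irx3 (-0.08), Ccnd1 (-0.13), Id1 (-0.05), Aldh1a2 (-0.06), Stra6 (-0.40), Crabp2 (-0.39), Sema6a (-0.09), Calml4 (-2.98), Clic6 (-5.32), Folr1 (-2.58), Hspb1 (-0.33) and Egr1 (-1.41). The retinoic acid list (-0.39) and the choroid plexus list (-2.98) reversed as well. Col3a1, Lum, Col1a2, Col1a1 and Aldh1a2 are themselves part of the meninges mean, so their change with it was largely fixed by construction. The 5 genes, named after their values were seen, were Col3a1, Dbx1 (4.90), Ddit4 (3.71), Nop58 (1.91) and Scml4 (2.72).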

Other observations

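The genes of this paragraph and the relations between lists below were chosen after their values were seen. Dbx1, a homeobox gene of progenitors at the borders of the telencephalon, rose from 4.5 ± 0.29 to 8.05 ± 0.32 (log2, mean ± SD, n = 5 each), a difference of 3.55 ± 0.16 (SE, limma adjusted p = 1.15e-08). The ligand genes Bmp4 (1.96 ± 0.13), Bmp5 (1.91 ± 0.13), Bmp6 (2.38 ± 0.16) and Bmp7 (1.14 ± 0.13) rose and Bmp2 (0.13 ± 0.12) did not pass, with no test of the family as a group, on the same arrays whose meninges mean was 3.25 higher. Lxn rose from 7.97 ± 0.21 to 10.38 ± 0.05 (2.41 ± 0.09). Hmga2, a chromatin gene of young progenitors, fell by 1.06 ± 0.09, the homeodomain-only gene Hopx by 0.94 ± 0.07 and the growth factor receptor gene Fgfr3 by 0.85 ± 0.08.

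A set of 391 genes, 355 higher and 36 lower, passed in the same direction with all arrays, with each array left out, with the Xist level or the choroid plexus mean in the model, against wild type 5 alone, and without wild type 1 and 5. These settings do not include the meninges mean as a covariate. Of the set, 245 rose and 17 fell at least 2-fold. It held Dct, Nxph2, Dmrta1, Rpp25, Sst, Rbm20, Nxph1, Eya4, Rec8, Pax6, Gas1, Hey1 and Fzd8 among the lower genes and Rarb, Cdkn1c, Lmo1, Id3, Sp5, Tshz2, Dbx1, Bmp4, Bmp5 and Bmp6 among the higher ones. The higher ones also held genes of the meninges, vessel and microglia lists, such as Slc6a13, Foxd1, Dcn, Pdgfrb, Cldn5, Tek and C1qc. Prr15, Lhx6, Ebf3, Sox6, Npy, Hes1, Cdon and Bmp7 were not in it.

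The mean of the ganglionic eminence list varied between arrays of a group together with other lists of ventral neurons. Over 10 arrays, after each group's mean was taken off, it was correlated with the GABA list at Pearson r = 0.85 (exact permutation within groups p = 0.00667, adjusted 0.022 over 6 relations) and Spearman rho = 0.84 (exact permutation p = 0.00771, adjusted 0.0463). For the striatal list r was 0.82 (exact permutation p = 0.011, adjusted 0.022) and rho 0.72 (exact permutation p = 0.0471, adjusted 0.0942). For the cholinergic list r was 0.88 (exact permutation p = 0.00958, adjusted 0.022) and rho 0.77 (exact permutation p = 0.026, adjusted 0.078). Without wild type 22 and 21, the arrays farthest from the median, r was 0.69, 0.74 and 0.55. For the cortical, meninges and choroid plexus lists r was -0.11, 0.05 and -0.23 (exact permutation p = 0.711, 0.953 and 0.704, adjusted 0.853, 0.953 and 0.853), rho was -0.32, 0.30 and 0.01 (exact permutation p = 0.366, 0.519 and 0.935, adjusted 0.549, 0.623 and 0.935), and without those arrays r was 0.12, 0.06 and -0.20.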
